A study of Mus musculus with 2 samples.

How the data were processed

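Gene expression was measured on 2 two-colour Agilent 60-mer arrays of mouse ESCs. On each array WT RNA carried Cy3 and RNA of cells labelled HDAC6 overexpression carried Cy5, so both arrays have the same dye orientation and there is no dye swap. Per the labels' protocols, total RNA was extracted with Trizol and amplified linearly before dye labelling. The labels call the arrays biological replicates. The names of the deposited files give the same number to the WT and to the overexpressing material on both arrays, so whether the RNA came from separate cultures is not settled here. If it did not, the p-values measure a technical spread.

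Per the file headers, the authors' scans were read with Agilent Feature Extraction 11.5.1.1, and each array has 62976 spots, of which 3671 are controls. The deposited files hold the raw median intensity of each spot and of its local background in both channels, with no normalization. They also hold processed intensity values, which per the file headers were background-subtracted and dye-normalized (linear and lowess). The deposited log10 ratio is that of the processed Cy5 over the processed Cy3 signal and is set to 0 where neither channel is above background. A p-value from the error model of Feature Extraction stands beside each deposited ratio. The deposited series table holds log2 values for 55821 probes. Set against the scanner ratios, its columns correlated at -1.000 and -0.999 with slopes of -1.000 and -1.000, so its values are log2 ratios of WT over overexpression. Its column medians were -0.0074 and 0.062, scale and direction are settled by this comparison, and whether any further centring was applied stays unknown. Both arrays lie on 1 slide and were scanned together, so there is no batch to test.

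From the raw median intensities, background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, then each array was normalized with loess, with control and outlier-marked spots at weight 0. The plan had named mean spot signals, which are not a column of the files used here, so median signals took their place. Outlier-marked spots (269 and 313) were left out, no spot was saturated, and the spots of a probe were averaged. Of 55681 probes other than controls, 26762 were paired with 1 gene symbol through their unversioned accession in a RefSeq table of assembly GRCm38.p6, 0 with several and 28919 with none. The array's own grid was built on another assembly, so no coordinates are given and the table served only for names, chromosomes and gene order. Each gene was represented by its probe of highest mean intensity, and kept when that probe was well above background in one same channel on both arrays, which left 16062 genes.

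The log2 ratio against 0 was tested with limma (lmFit and eBayes, intercept only, two-sided), with Benjamini-Hochberg adjustment. The prior had 8.71 degrees of freedom beside the 1 residual degree of freedom, and the typical standard error of a mean log2 ratio was 0.090. A count of genes at least 2-fold changed on both arrays stands beside the test. A gene not well above background in one channel on both arrays has only a bound there, computed per channel after loess and Aquantile normalization, with the dim channel at its own level or at the 95th percentile of probes not well above background, whichever was higher. This floor was chosen after the data were examined. The precision of each value is limited by the number of arrays. Copies of the same probe on one array had an SD of 0.062 (replicate 1) and 0.063 (replicate 2) in log2 ratio.

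Fixed before the data were examined were 38 gene lists, the design, the alternatives and the rule for naming genes. Lists with at least 5 measured members were tested with camera (preset correlation 0.01), with camera with an estimated correlation, with fry, whose PValue asks whether a list's genes move one way on balance, and against 10000 random lists matched on intensity. The naming rule takes Hdac6, the 12 highest and 12 lowest mean log2 ratios among genes past the threshold with the same sign on both arrays and a proper name, up to 4 members of each list with the largest absolute log2 ratio past the threshold (up to 2 by moderated statistic where none passed), and Pou5f1, Nanog, Sox2, Zfp42 and the Zscan4 members. Lists are judged over all genes and with counts adjusted over the list alone.

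Chromosome medians used genes well above background in both channels and were tested by rotating the values along the gene order 9999 times. The fit was tested on simulated data for this comparison, with 16062 genes, 200 of them changed, in 20 draws. On average it recovered 79.4% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 4. False calls made up a median of 10.2% and at most 33.4% of all calls, above the nominal 5%. The estimated prior degrees of freedom ranged from 7.51 to 1706 where 8.71 had been simulated. A simulated shift of 1 list and of 1 chromosome was recovered with no other of the 38 lists or 20 chromosomes called. Each was 1 draw of independent values with nothing else shifted. It does not show how these tests behave with correlated list members or several shifted chromosomes.

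Alternatives covered the Agilent processed ratios, no background correction, normexp offset 16, median centring in place of loess, scale normalization between arrays, the filter on dim probes (none, or both channels), keeping outlier-marked spots, the mean over a gene's probes, an intensity trend with a robust prior, the series table, other thresholds and tests, and leaving out each array. Left out of the gene comparisons were control spots and probes with no gene symbol. Summaries were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, with statmod 1.5.0 and data.table (version 1.17.8) in R.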

Results

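The series asked how raised HDAC6 changes gene expression in mouse embryonic stem cells (ESCs), the pluripotent cells derived from the early embryo. HDAC6 is a mainly cytoplasmic deacetylase whose known substrates include alpha-tubulin and the chaperone Hsp90. The ESCs were of the B6C3F1 strain, were grown on growth-arrested mouse embryonic fibroblasts (feeders) with the cytokine LIF, and were used at passage 26. Total RNA of wild-type (WT) ESCs, labelled with Cy3, and of ESCs labelled as overexpressing HDAC6, labelled with Cy5, was hybridised together on each of 2 Agilent arrays. The labels call the arrays biological replicates 1 and 2. Well above background were 68.8% of the probes in the WT channel and 68.7% in the overexpression channel of replicate 1, against 68.1% and 68.6% in replicate 2. Median raw signals were 459 (WT) and 432.5 (overexpression) in replicate 1 and 449.5 and 462 in replicate 2, over median backgrounds of 53 to 58. Each value below is the log2 ratio of the overexpression channel over the WT channel, the reverse of the deposited series table, which runs as WT over overexpression. It is given as the mean of the 2 arrays ± SD, with n = 2 throughout. The number of arrays limits the precision, and the same dye orientation on both leaves dye effects in every ratio.

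In the overexpression channel, genes of the primitive endoderm rose most among the fixed gene lists, among them the endocytic receptor gene Cubn at 39.4-fold (5.30 ± 0.032). Fibroblast markers, Hox genes and trophectoderm genes were higher with them, and genes of the interferon response and of cholesterol synthesis were lower. These list calls were made with a preset correlation. With an estimated correlation each list had a camera adjusted p = 0.92, but that test had 1 residual degree of freedom and little power to call any list. The call for cholesterol synthesis was also lost with the Agilent processed ratios, with median centring and with the mean over probes. Whether a larger share of feeder RNA accounts for the rise of the fibroblast markers and Hox genes was not tested. Genes of chromosome 11 were lower together, with a median log2 ratio of -0.49. Hdac6 itself was not higher. The brighter of its 2 probes had a log2 ratio of 0.15 in replicate 1 and -0.055 in replicate 2, a mean of 0.046 ± 0.14 (limma adjusted p = 0.7). The other probe had 0.16 and -0.0050. Both probes were bright, with a WT signal above 91.3% (brighter probe) and 88.5% of the measured genes. Centring each array on its median in place of the loess step, which removes a trend of the ratio with brightness, gave 0.52 (limma adjusted p = 0.0010), and over 12 alternative settings this p ranged from 0.0010 to 0.73. Where the probes lie relative to the introduced sequence is not known here, so these values do not check the labels, and directions below refer to the channel as labelled.

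Among 16062 genes tested with limma, 3559 were higher and 5540 lower in the overexpression channel at an adjusted p under 0.05, which is 56.6% of the genes. The counts of list members given below stand against these totals. A list with shares near those over all genes does not stand out by its counts. A change of at least 2-fold on both arrays was met by 287 genes that were higher and 455 that were lower, and all of these were also past the limma threshold. The Agilent processed ratios gave 487 and 706 such genes, and replicate 2 alone 627 and 716. The log2 ratios of the 2 arrays correlated across genes with Pearson r = 0.929 and Spearman rho = 0.899, and 86.1% of genes had the same sign on both. Genes are not independent replicates, and dye effects shared by the arrays raise these values as shared biology does. The SD of the difference between arrays was 0.22 over genes, against an SD of 0.55 for the mean ratio. These p-values rest on 1 residual degree of freedom and measure only the spread between these 2 arrays, whose deposited files number the WT and the overexpressing material alike. In simulated data with 200 changed genes among 16062, a median of 10.2% of the calls were false, and 33.4% in the worst of 20 draws. That share depends on how many genes change and is not an estimate for the calls above. Median centring in place of loess gave 4877 higher and 4811 lower genes, and a limma test against a 1.5-fold change, chosen after seeing the data, gave 547 and 835.

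**Figure D1:**
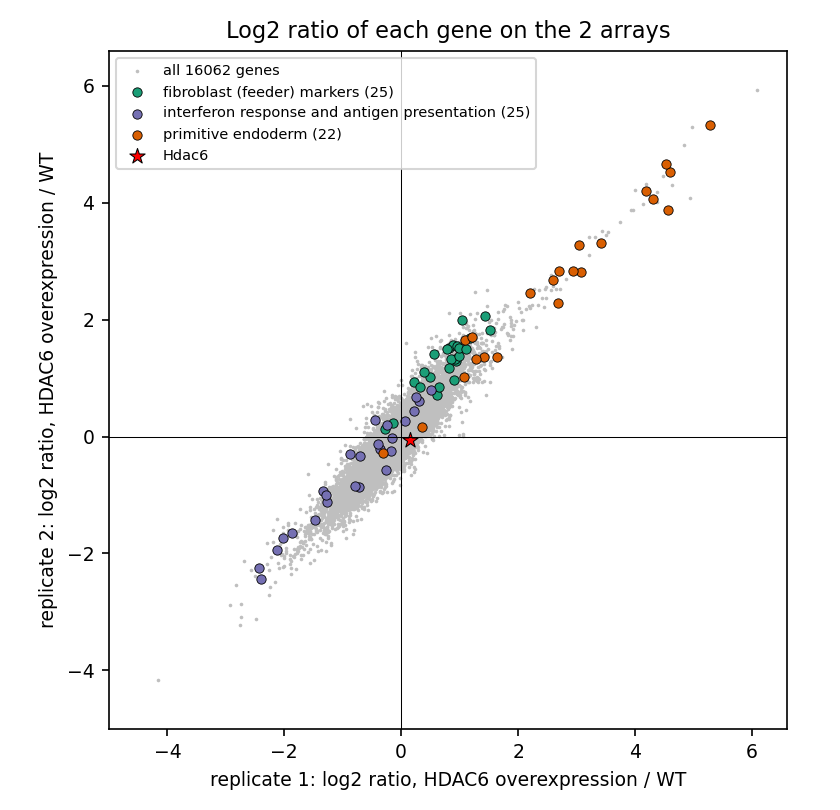
Log2 ratio (HDAC6 overexpression over WT) of each of the 16062 genes on replicate 1 (x axis) and replicate 2 (y axis); coloured points are members of 3 of the fixed gene lists, and the star is Hdac6. Most primitive endoderm genes lie at the upper right, among them Cubn at 5.30, while Hdac6 lies near 0 at 0.15 and -0.055.

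Of the 38 gene lists, the largest median rise was that of the primitive endoderm, the extra-embryonic lineage that lines the blastocyst cavity. Of this list, 21 of 22 measured members were higher and 1 lower (adjusted over the list alone 21 higher and 1 lower), and 20 were at least 2-fold higher on both arrays. The median log2 ratio was 2.70 (2.69 in replicate 1 and 2.74 in replicate 2). The transcription factor genes Gata4 and Foxa2 rose 24.2-fold (4.60 ± 0.091) and 23.7-fold (4.57 ± 0.055). The only other probe of Cubn had 4.34. The adjusted p of Cubn, Gata4 and Foxa2 were 6.4e-10, 1.0e-09 and 1.0e-09. Ttr, which encodes the carrier protein transthyretin, was not well above background in the WT channel and was at least 13.0-fold higher. Such bounds set the mean of the brighter channel against the 95th percentile of probes not well above background in the other channel, and are open to dye bias. The bound of Ttr lies above the list median, which is therefore the same with it. In the camera test, which compares the moderated statistics of the list with those of the other genes, the list was higher with adjusted p = 1.2e-18. With an estimated correlation the adjusted p was 0.92 for this list and for each of the other 37 lists, and fry gave adjusted p = 0.082. That correlation was estimated with 1 residual degree of freedom, and the smallest unadjusted p of that camera test was 0.063, for this list. The test had little power here, so the 0.92 given beside each called list neither backs a call nor counts against it.

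Beyond that list, the highest log2 ratio among genes with more than a bound was that of Srgn, the core protein gene of a secretory granule proteoglycan, at 64.4-fold (6.01 ± 0.11, adjusted p = 5.2e-10). Nostrin followed at 5.13 ± 0.23. The calcium-binding protein gene S100g had 4.51 ± 0.61, Tfec, of the MiT family of transcription factors, 4.47 ± 0.0092, the hexokinase-domain gene Hkdc1 4.29 ± 0.14, and the bHLH factor gene Tcf23 4.24 ± 0.022. Nxf7, of the nuclear RNA export factor family, had 4.26 ± 0.10, with its WT signal well above background on 1 of the 2 arrays. Its mean WT log2 level of 7.29 lay below the floor of 7.38 used for bounds in that channel, so its ratio is uncertain. The water channel gene Aqp8 and the glucuronosyltransferase gene Ugt2b34 were not well above background in WT and were at least 28.1-fold and 19.3-fold higher by their brightest probes. As these are bounds, the rank of both genes against Srgn is not known. The only other probe of Aqp8 had a log2 ratio of 2.56, so its bound holds for 1 probe only. The Agilent processed ratios gave larger log2 values, of 6.18 for Nostrin, 5.403 for S100g, 5.27 for Tfec, 5.30 for Hkdc1, 5.28 for Tcf23 and 5.69 for Nxf7. Among the highest, 0 names were passed over as a clone or locus number.

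Markers of fibroblasts, the feeder cell type, were higher too. In that list 23 of 25 measured members were higher and 0 lower (adjusted over the list alone 23 higher and 0 lower). Col1a2, a collagen chain gene, had 1.75 ± 0.44, S100a4 1.67 ± 0.21, the smooth muscle actin gene Acta2 1.52 ± 0.68 and Thy1 1.43 ± 0.36. The median was 0.85 in replicate 1 and 1.32 in replicate 2 (camera adjusted p = 1.3e-11; adjusted p = 0.92 with an estimated correlation). Hox genes, which set position along the body axis, had medians of 0.46 and 0.86. In that list 23 of 27 measured members were higher and 3 lower (adjusted over the list alone 23 higher and 3 lower), among them Hoxc9 at 1.496 ± 0.15, Hoxa10 at 1.36 ± 0.017, Hoxb6 at 1.36 ± 0.26 and Hoxb9 at 1.15 ± 0.39 (camera adjusted p = 2.8e-07; adjusted p = 0.92 with an estimated correlation). In the NF-kB target list 8 of 15 measured members were higher and 3 lower (adjusted over the list alone 8 higher and 3 lower). The cytokine gene Cxcl1 had 1.92 ± 0.014, Il6 1.79 ± 0.23 and Ccl2 1.51 ± 0.41, while Cxcl10, an interferon-induced chemokine gene, fell by 2.01 on the log2 scale. The camera adjusted p was 0.0079 for this list, and the adjusted p = 0.92 with an estimated correlation. The Agilent processed ratios gave 2.14 for Hoxa10, and median centring gave 2.14 for Acta2. Beside the Hox and NF-kB lists stands the fibroblast median of 1.11 over both arrays. Whether a larger share of feeder RNA accounts for the rises in these 3 lists was not tested, so they are not shown to be changes within the ESCs.

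Trophectoderm genes, of the lineage that forms the placenta, rose with them. In that list 14 of 18 measured members were higher and 0 lower (adjusted over the list alone 14 higher and 0 lower), with Tead4 at 1.21 ± 0.025, the keratin gene Krt7 at 1.17 ± 0.12, Eomes at 0.997 ± 0.12 and Cdx2 at 0.99 ± 0.32 (camera adjusted p = 3.0e-06; adjusted p = 0.92 with an estimated correlation). For mesendoderm 10 of 18 measured members were higher and 5 lower (adjusted over the list alone 10 higher and 5 lower), and the camera test did not call the list (adjusted p = 0.069). Its changed members included Foxa2, Cer1, an inhibitor of Nodal signalling that was at least 4.13-fold higher over a WT signal not well above background, and the receptor gene Kdr, which fell (-1.05 ± 0.14). The only other probe of Kdr had -0.085, and the mean over its probes was -0.56.

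The genes that fell most were of several kinds. Nxf3, another nuclear RNA export factor gene, had -4.17 ± 0.0029, a fall of 18.0-fold (adjusted p = 1.3e-09). The testis cytochrome c gene Cyct had -2.99 ± 0.33, the embryonic myosin heavy chain gene Myh3 -2.92 ± 0.24, Ushbp1 -2.80 ± 0.45, the phosphatase gene Dusp26 -2.49 ± 0.31, the serpin gene Serpina3m -2.43 ± 0.20, Ct55 -2.41 ± 0.39 and the keratin gene Krt12 -2.40 ± 0.23. Dnajc5g was not well above background in the overexpression channel and was at least 5.55-fold lower. The interferon-induced GTPase genes Tgtp2 and Gbp4 had -2.69 ± 0.20 and -2.44 ± 0.08, and the only other probe of Tgtp2 went the opposite way. The Agilent processed ratios gave -5.22 for Nxf3, and the mean over probes gave -1.24 for Tgtp2 and -1.59 for Ushbp1. The only other probe of Krt12 had -1.41. Among the lowest genes, 1 name that is only a clone or locus number was passed over.

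Genes of the interferon response and antigen presentation fell as a group, where 4 of 25 measured members were higher and 16 lower (adjusted over the list alone 4 higher and 17 lower). Oasl2 had -2.41 ± 0.028, Gbp3 -2.34 ± 0.13, the antiviral gene Rsad2 -2.04 ± 0.13 and the immunoproteasome subunit gene Psmb8 -1.87 ± 0.20. Camera gave adjusted p = 0.0079, and adjusted p = 0.92 with an estimated correlation. The median was -0.71 in replicate 1 and -0.34 in replicate 2. Cholesterol synthesis genes were lower as well, where 2 of 21 measured members were higher and 14 lower (adjusted over the list alone 2 higher and 14 lower). Hmgcs1, an early enzyme gene of the pathway, had -0.83 ± 0.035, the regulator gene Insig1 -0.79 ± 0.0022, Lss -0.70 ± 0.038 and Mvd -0.70 ± 0.022. Camera gave adjusted p = 0.044, and adjusted p = 0.92 with an estimated correlation, and the call was lost with the Agilent processed ratios (0.057), with median centring (0.17) and with the mean over probes (0.081). Median centring took Hmgcs1 to -0.24. Over 12 settings it ranged from 0.019 to 0.17.

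Pluripotency genes moved in both directions. Of the core list, 5 of 19 measured members were higher and 6 lower (adjusted over the list alone 6 higher and 6 lower), and camera did not call it (adjusted p = 0.84). Pou5f1, which encodes OCT4, had 0.37 ± 0.14 (adjusted p = 0.0076) and missed the threshold with the Agilent processed ratios, at 0.22 (adjusted p = 0.12; 3.7e-06 to 0.12 over 12 settings). Sox2 had 0.16 ± 0.085 and Nanog -0.044 ± 0.079, neither past the threshold, and median centring gave 0.59 and 0.92, both past it. The Agilent processed ratios gave -0.29 for Nanog, just past it. Tdgf1, a Nodal co-receptor gene, fell (-0.86 ± 0.0058, and -0.15 without a call under median centring), as did Fbxo15 (-0.80 ± 0.078) and Dppa5a (-0.52 ± 0.034), while Mybl2 rose (0.51 ± 0.13). Median centring gave 1.06 for Pou5f1 and 1.16 for Mybl2. In the naive pluripotency list 9 of 18 measured members were higher and 4 lower (adjusted over the list alone 9 higher and 4 lower), led by the transcription factor genes Tbx3 at 2.67 ± 0.15 and Tfcp2l1 at 1.496 ± 0.15 and by Tcl1 at 1.21 ± 0.049, whereas Pramel7 had -1.05 ± 0.16 and Zfp42 -0.52 ± 0.035. Camera called the naive list higher (adjusted p = 0.014; adjusted p = 0.92 with an estimated correlation), but not with the Agilent processed ratios (0.093; 0.0023 to 0.093 over 12 settings). LIF and STAT3 targets were called higher (adjusted p = 0.012; adjusted p = 0.92 with an estimated correlation), where 8 of 16 measured members were higher and 1 lower (adjusted over the list alone 8 higher and 2 lower), among them the LIF-family receptor gene Osmr at 1.12 ± 0.10, Klf4 at 0.92 ± 0.024 and Junb at 0.80 ± 0.41. The fibroblast median beside this list was 1.11, and feeder RNA was not tested as a source of its rise. Genes of the formative and primed states were not called (adjusted p = 0.39), though 4 of 16 measured members were higher and 10 lower (adjusted over the list alone 4 higher and 10 lower). Lef1 had -1.37 ± 0.27, Zic2 -1.32 ± 0.15 and Sox3 -0.97 ± 0.22, while Fgf5 had 0.96 ± 0.47. Of the 2-cell-like genes, expressed in a rare ESC state, 1 of 20 measured members was higher and 6 lower (adjusted over the list alone 1 higher and 2 lower). The 3 measured Zscan4 members did not pass, with Zscan4a at 0.16 ± 0.35, Zscan4c at 0.18 ± 0.27 and Zscan4f at 0.10 ± 0.27. Usp17lb (-0.70 ± 0.26) fell, Zfp352 (0.71 ± 0.18) rose, and Sp110 had -1.01 ± 0.23, which turned to 0.95 when outlier-marked spots were kept.

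**Figure D2:**
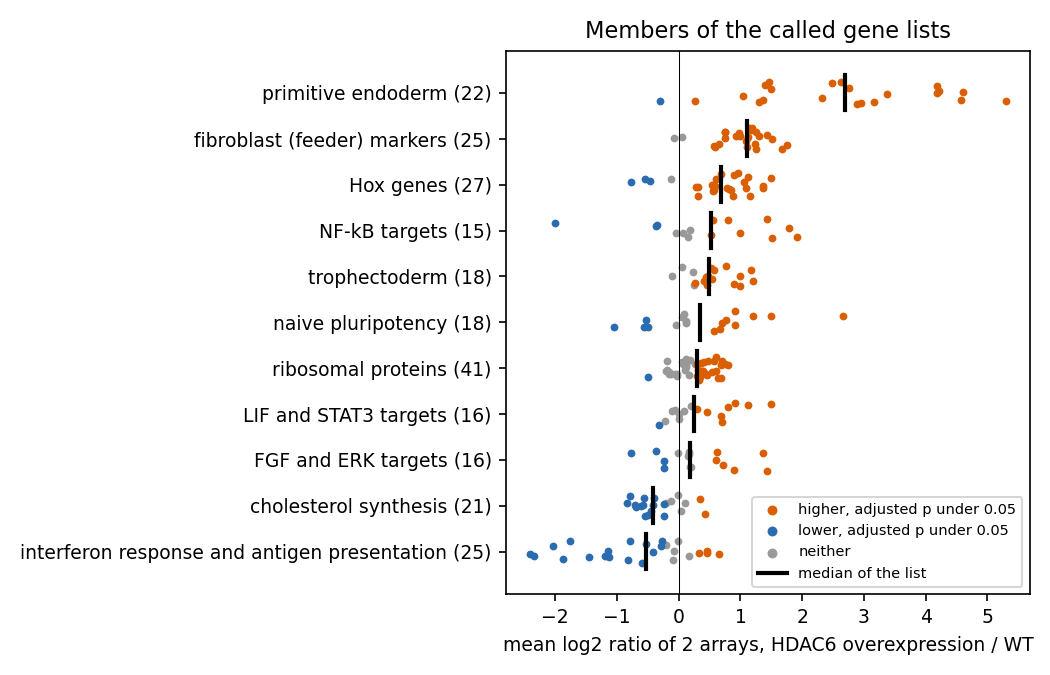
Mean log2 ratio (HDAC6 overexpression over WT, 2 arrays) of each measured member of the 11 lists that camera called with the preset correlation; colours mark the limma call and black bars the list median. Medians run from -0.52 in the interferon list to 2.70 in the primitive endoderm list.

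Targets of signalling pathways were mixed. For FGF and ERK 6 of 16 measured members were higher and 4 lower (adjusted over the list alone 6 higher and 4 lower), with Spry4 at 1.43 ± 0.049, Fosl1 at 1.37 ± 0.46, Myc at 0.90 ± 0.39 and Etv5 at -0.77 ± 0.13 (camera adjusted p = 0.044; adjusted p = 0.92 with an estimated correlation), and the call was lost with the Agilent processed ratios (0.057; 0.033 to 0.070 over 12 settings). The fibroblast median beside this list, too, was 1.11, and feeder RNA was not tested as a source of its rise either. For Wnt 7 of 17 measured members were higher and 8 lower (adjusted over the list alone 7 higher and 8 lower). Dkk1, a secreted Wnt inhibitor gene, had 3.32 ± 0.15 and Cdx1 1.47 ± 0.91, whereas Lef1 and Tcf7 (-1.25 ± 0.052) fell, and the list was not called (adjusted p = 0.84). Dkk1 had 4.23 with the Agilent processed ratios, and Cdx1 had 0.83 in replicate 1 and 2.11 in replicate 2. The Wnt list had a median of -0.39 in replicate 1 and of 0.16 in replicate 2. For Nodal, TGF-beta and BMP 10 of 17 measured members were higher and 5 lower (adjusted over the list alone 10 higher and 5 lower; camera adjusted p = 0.21). Id3 had 1.095 ± 0.60 and Msx2 0.93 ± 0.052.

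Other lineage lists were not called, although some members changed strongly. In neuroectoderm 2 of 18 measured members were higher and 9 lower (adjusted over the list alone 2 higher and 10 lower; camera adjusted p = 0.21), with the neural transcription factor genes Sox1 at -2.11 ± 0.14 and Pax6 at -1.85 ± 0.24 and Hes5 at -1.13 ± 0.072. The only other probe of Sox1 went the opposite way, and the mean over probes gave -1.04. Cardiac muscle genes included Actc1, the cardiac actin gene, at -1.97 ± 0.087, Nkx2-5 at -1.61 ± 0.054, Myh6 at -1.28 ± 0.041 (-0.59 as the mean with its only other probe, which went the opposite way) and Myl4 at -1.08 ± 0.037, and 5 of 16 measured members were higher and 8 lower (adjusted over the list alone 5 higher and 8 lower; camera adjusted p = 0.73). Among imprinted genes 3 of 27 measured members were higher and 11 lower (adjusted over the list alone 3 higher and 11 lower; camera adjusted p = 0.17). Mest had -2.02 ± 0.026, Nnat -1.29 ± 0.40 and Cdkn1c -0.997 ± 0.18, against Igf2 at 1.15 ± 0.12. In the germline list 3 of 20 measured members were higher and 7 lower (adjusted over the list alone 2 higher and 7 lower; camera adjusted p = 0.84), among them Stra8 at -0.98 ± 0.33, Sycp1 at -0.95 ± 0.023 and Tex19.1 at -0.91 ± 0.056, and Tdrd1, not well above background in the overexpression channel, was at least 1.07-fold lower. Epithelial junction and keratin genes split, where 5 of 18 measured members were higher and 7 lower (adjusted over the list alone 5 higher and 7 lower; camera adjusted p = 0.88). Krt19 had -1.24 ± 0.094 and the junction gene Ocln -1.02 ± 0.00047, while Dsp had 0.98 ± 0.0061 and Cldn4 0.64 ± 0.20.

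Lists around the known substrates and partners of HDAC6 held few large changes and none was called. Of the other histone deacetylases and sirtuins, 5 of 17 measured members were higher and 5 lower (adjusted over the list alone 5 higher and 5 lower; camera adjusted p = 0.73). Hdac9 had -0.59 ± 0.0087, Sirt7 -0.53 ± 0.10, Hdac10 0.56 ± 0.04 and Hdac4 0.53 ± 0.005. For tubulins and microtubule regulators 2 of 23 measured members were higher and 8 lower (adjusted over the list alone 2 higher and 8 lower; camera adjusted p = 0.73). Tubb3 had -0.95 ± 0.26, Tuba1a -0.88 ± 0.21 and Tubd1 -0.67 ± 0.14, against the tau gene Mapt at 1.25 ± 0.18. Primary cilium genes showed 0 higher and 10 lower of 20 measured (adjusted over the list alone 0 higher and 9 lower; camera adjusted p = 0.19), among them the kinesin gene Kif3a at -0.85 ± 0.007, Mks1 at -0.68 ± 0.10 and Arl13b at -0.56 ± 0.069. For heat shock chaperones 6 of 18 measured members were higher and 3 lower (adjusted over the list alone 6 higher and 3 lower; camera adjusted p = 0.28). Cryab had 1.15 ± 0.57, the collagen chaperone gene Serpinh1 0.90 ± 0.061 and Hspa4l -0.93 ± 0.0079. In the unfolded protein response 8 of 20 measured members were higher and 5 lower (adjusted over the list alone 8 higher and 5 lower; camera adjusted p = 0.38). Xbp1 had -0.92 ± 0.05, Canx -0.88 ± 0.036, Calr 0.73 ± 0.17 and Hsp90b1 0.64 ± 0.047, and median centring gave 1.33 for Calr. For autophagy and aggresome genes 5 of 23 measured members were higher and 7 lower (adjusted over the list alone 5 higher and 7 lower; camera adjusted p = 0.84). Ulk2 had -0.69 ± 0.13, Becn1 -0.69 ± 0.071 and Tfeb 0.75 ± 0.34. For the proteasome 6 of 31 measured members were higher and 13 lower (adjusted over the list alone 6 higher and 13 lower; camera adjusted p = 0.73). Psmd3 had -0.83 ± 0.036 and Psmb6 -0.78 ± 0.077, while Psmd8 had 0.59 ± 0.29. Median centring turned the proteasome list to a higher call and took Psmd3 (-0.20) and Psmb6 (-0.15) short of the threshold.

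Chromatin and chromosome-end lists were not called. The Tip60-p400 complex had 0 higher and 6 lower of 17 (adjusted over the list alone 0 higher and 6 lower; camera adjusted p = 0.74). Its share of lower genes was near that over all genes (5540 of 16062). Ep400 had -0.54 ± 0.16, Actl6a -0.44 ± 0.024 and Dmap1 -0.39 ± 0.017, which turned to 0.031 under median centring, where Actl6a had -0.017. In the DNA methylation and Polycomb list 5 of 21 measured members were higher and 5 lower (adjusted over the list alone 5 higher and 5 lower; camera adjusted p = 0.84). Dnmt3l, a cofactor of DNA methyltransferases, had 1.04 ± 0.039, and the Polycomb genes Suz12 -1.02 ± 0.12, Ezh1 -0.996 ± 0.054 and Cbx2 -0.75 ± 0.034. For telomere maintenance 3 of 23 measured members were higher and 8 lower (adjusted over the list alone 3 higher and 8 lower; camera adjusted p = 0.84). Ctc1 had -0.72 ± 0.14, Nhp2 -0.70 ± 0.054 and Pot1a 0.46 ± 0.0051. Cytosolic ribosomal protein genes were called higher (camera adjusted p = 9.3e-05; adjusted p = 0.92 with an estimated correlation). In that list 22 of 41 measured members were higher and 1 lower (adjusted over the list alone 22 higher and 1 lower). Rpl7 had 0.80 ± 0.036, Rpl28 0.74 ± 0.22 and Rps13 0.69 ± 0.11. Median centring gave 1.47, 1.60 and 1.56 for them. Rpl15 had 0.70 ± 0.072, and its only other probe went the opposite way (-0.52).

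The respiratory chain, glycolysis, hypoxia, oxidative stress, p53 and mitosis lists were not called. Mitochondrial respiratory chain genes had 7 higher and 8 lower of 35 (adjusted over the list alone 7 higher and 8 lower; camera adjusted p = 0.73). Cox6b1 had 0.89 ± 0.12 and Sdha -0.55 ± 0.071. Median centring took Sdha to -0.13 without a call and Cox6b1 to 1.51. For glycolysis 5 of 19 measured members were higher and 5 lower (adjusted over the list alone 5 higher and 5 lower; camera adjusted p = 0.84). Aldoc had -1.498 ± 0.34, the lactate exporter gene Slc16a3 -1.30 ± 0.33 and the glucose transporter gene Slc2a1 -1.004 ± 0.32, and median centring gave -0.68 for Slc16a3 and -0.35 for Slc2a1. Hypoxia response genes included Ankrd37 at -1.47 ± 0.22, Ndrg1 at -1.25 ± 0.38, Egln3 at -1.15 ± 0.37 and P4ha1 at 0.87 ± 0.12, and 6 of 19 measured members were higher and 11 lower (adjusted over the list alone 6 higher and 11 lower; camera adjusted p = 0.49). For the oxidative stress response 3 of 18 measured members were higher and 7 lower (adjusted over the list alone 3 higher and 7 lower; camera adjusted p = 0.84). Gpx1 had 1.0997 ± 0.18, Slc7a11 -0.88 ± 0.032 and Nqo1 -0.65 ± 0.13, and median centring gave 1.85 for Gpx1. For p53 targets 8 of 20 measured members were higher and 3 lower (adjusted over the list alone 8 higher and 3 lower; camera adjusted p = 0.16). Fas had 0.87 ± 0.22, Cdkn1a 0.83 ± 0.30 and Sesn1 -0.62 ± 0.14. For mitosis and DNA replication 4 of 30 measured members were higher and 8 lower (adjusted over the list alone 4 higher and 7 lower; camera adjusted p = 0.84). Top2a had -0.72 ± 0.024, Gins2 -0.68 ± 0.065 and Mcm7 0.55 ± 0.037. Median centring took Gins2 to -0.13 without a call and Mcm7 to 1.32, and turned this list to a higher call. It also called the core pluripotency, heat shock, respiratory chain, glycolysis and p53 lists higher and the neuroectoderm list lower. The mean log2 ratio lay below 0 while camera placed the list above the other genes for core pluripotency, 2-cell-like, epithelial, Polycomb, autophagy, respiratory chain and glycolysis genes. The mean of all genes was -0.071. The means of the glycolysis (-0.14) and epithelial (-0.076) lists lay below that too, so it does not account for their direction. Camera compares moderated statistics and not mean log2 ratios, so its direction can differ from that of the mean. The medians of the core pluripotency (0.056) and respiratory chain (0.023) lists were above 0, and the Wnt list had a mean of 0.076 with a median of -0.073. The deacetylase list had a mean of 0.004 with a median of -0.016.

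Many of the genes that fell lay on a few chromosomes. Among 15407 genes well above background in both channels, the 1294 genes of chromosome 11 had a median log2 ratio of -0.51 in replicate 1 and -0.48 in replicate 2, the 827 genes of chromosome 8 had -0.26 and -0.26, and the 862 genes of chromosome 1 had 0.21 and 0.20. The other autosomes and X had medians, over the mean of the arrays, between -0.11 and -0.015. Chromosomes 8 and 11 held 163 of the 414 genes in this set that were at least 2-fold lower on both arrays, where their share of genes would give 57.0. Rotating the values along the gene order gave a permutation p of 2e-04 for chromosome 11 (adjusted p = 0.0040 over 20 chromosomes), 0.12 for chromosome 8 and 0.064 for chromosome 1. The rotated values included the shifted genes of chromosome 11, which raise the p of a less shifted chromosome. The p of chromosomes 8 and 1 therefore do not decide whether these were shifted. Without the genes of chromosomes 1, 8 and 11, a choice made after seeing the data, 2856 genes were higher and 4007 lower by limma, and 244 and 277 were at least 2-fold changed on both arrays. Chromosome 11 holds Myh3, Tgtp2, Krt12, Aldoc, Slc16a3, Tcf7, Krt19, Myl4, Xbp1, Canx, Suz12, Ezh1, Cbx2, Ctc1, Nhp2, Becn1, Ulk2, Psmd3, Psmb6, Top2a, Kif3a, Mks1, Tubd1, Sirt7 and Tex19.1, named above as lower, and also Ccl2, Hoxb6, Hoxb9 and Mapt, named above as higher. It holds 6 of the measured autophagy genes, 6 of the proteasome genes, 5 of the Wnt targets, 4 of the telomere genes, 4 of the Polycomb list and 8 of the Hox genes. Chromosome 8 holds Zfp42, Sox1, Dusp26, Ushbp1, Ankrd37, Tubb3, Mvd, Gins2 and Nqo1, named above as lower, and Calr and Junb, named above as higher. Chromosome 1 holds Tfcp2l1, Rpl7 and Hdac4, named above as higher, and Sp110, named above as lower. Where a gene's ratio is near the shift of its chromosome, a change of its own cannot be told apart from that shift. With those 3 chromosomes left out, the Wnt targets were called higher (camera adjusted p = 0.035) and the FGF and ERK targets were not called (0.061), while the primitive endoderm (4.8e-14) and interferon (0.0057) lists were called as before. With an estimated correlation on the same genes, the adjusted p was 0.77 for each of these 4 lists, from a test with little power on 2 arrays.

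**Figure D3:**
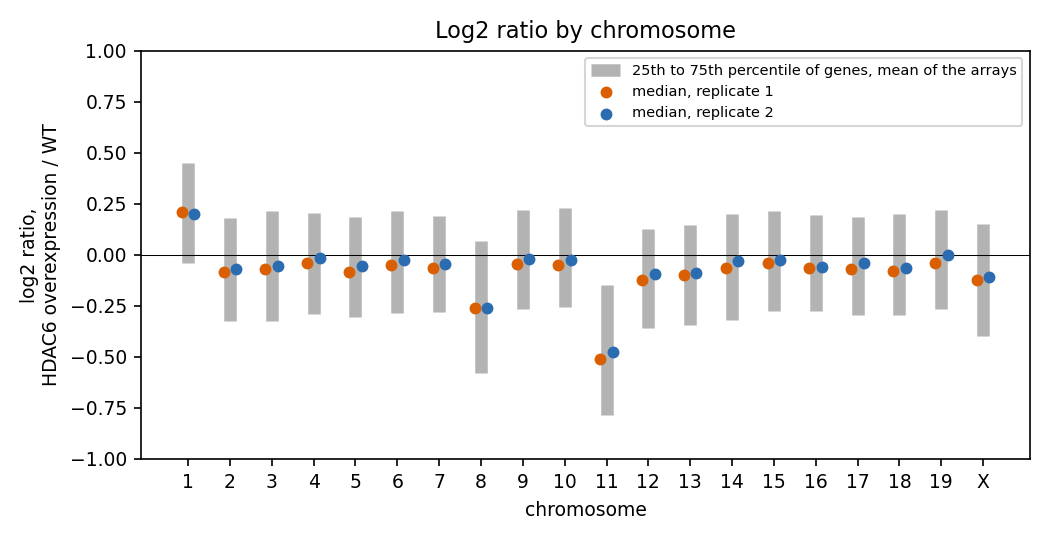
Median log2 ratio (HDAC6 overexpression over WT) of the genes of each chromosome in replicate 1 and replicate 2, with grey bars from the 25th to the 75th percentile of the mean of the arrays. Chromosome 11 lies lowest at -0.51 and -0.48, chromosome 8 next at -0.26, and chromosome 1 highest at 0.21 and 0.20.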

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

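The tests of the primitive endoderm against the fibroblast list and against random lists as a test of dye bias, of core pluripotency, of the direction of Hdac6, of its probes and of the segments of chromosome 11 were chosen after the results were seen.

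Signals outside the gene comparisons were found in 2 places. Among probes with no gene symbol, 17280 were well above background in one same channel on both arrays, and 140 of them were at least 2-fold higher and 214 at least 2-fold lower on both arrays. By limma, 4921 of these probes were higher and 3518 lower, the opposite balance to the 3559 higher and 5540 lower named genes. The spike-in controls, added at known ratios, read 2.86-fold too high in Cy5 over Cy3 in replicate 1 and 2.57-fold in replicate 2 by the statistics in the deposited files, with slopes of 0.722 and 0.714 of the observed on the expected log ratio.

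The rise of the primitive endoderm genes exceeded that of the feeder markers. The median of the 22 primitive endoderm genes lay 1.59 above that of the 25 fibroblast genes (permutation p = 2.0e-05). The first list was singled out for its largest median rise, with both medians already known. The sign of the difference and a small p were therefore given by that choice and carry no weight. Only the size of the difference argues against RNA of feeder fibroblasts as the source of the rise. The permutation p is over genes, which are not independent replicates, and does not measure the spread between cultures. Abundant fibroblast collagen genes such as Col1a2 (1.75) rose less than Gata4 (4.60). Several genes of the first list, such as Sparc and the collagen IV and laminin genes, are also made by fibroblasts. Dye bias that differs from probe to probe is argued against by the comparison with 10000 random lists matched on intensity. The median of the primitive endoderm list, whose members were fixed beforehand, lay at their 100th percentile. That percentile was known when the list was singled out. The comparison was run for every list, and its p adjusted over the lists was 0.00095, which allows for this choice. The 4 other probes of its genes, few as they are, also went the same way. A dye effect shared by the probes of this list stays open without a dye swap. A larger share of primitive endoderm cells in the culture may account for the rise, as may a rise within the ESCs. The core pluripotency median of 0.056, over members that went both ways, does not separate these, and neither does RNA of a whole culture.

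Hdac6 did not read higher in the channel labelled as overexpressing it. Loess is argued against as the cause, because without loess Hdac6 lay at the 69.6th percentile of the 500 genes nearest in intensity (80.2 in replicate 1 and 56.8 in replicate 2), whose median had itself moved to 0.35. Exchanged channel labels stay open, because a log2 ratio of 0.046 (SE 0.094) says nothing of the labels if the probes do not read the construct. That the 2 probes lie outside the transcript of the construct, or do not hybridise with it, may account for the result and cannot be told apart from a low level of the construct at the RNA level, since neither probe nor construct sequences were used here.

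Genes of chromosome 11 were lower together, and intensity-dependent normalization is argued against, because the shift against the other chromosomes was -0.24 in the intensity class where it was smallest and -0.50 where it was largest, of 5 classes with equal numbers of genes. A dye bias of gene-rich chromosomes is argued against, because the next 3 chromosomes by measured genes per length (7, 19 and 17) had shifts of -0.0020 or higher. A copy number difference of the chromosome between the cell populations is a candidate explanation, in which WT cells carry more copies. Each of 10 segments of chromosome 11 with equal numbers of genes was shifted, the least by -0.38, and the whole chromosome by -0.43, where 2 copies against 3 would give -0.58, or -0.42 after the spike-in slope. That slope was computed by Feature Extraction, whereas the -0.43 comes from the normexp and loess values. With the Agilent processed ratios the shift was -0.47, so the nearness of -0.42 and -0.43 carries no weight. It stays a hypothesis, found and tested on the same arrays, with no DNA measured. Whether such a difference came with HDAC6 or by chance in culture cannot be told from WT and overexpressing material alone. For the same reason, the other changes cannot be told apart from a difference between the cell populations that is unrelated to HDAC6.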

How the results depend on the processing

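With 2 arrays of one dye orientation, no setting removes a dye effect, and probes near background bound rather than measure a ratio. The limma test against 1.5-fold and the removal of chromosomes 1, 8 and 11 were chosen after seeing the data. An alternative with probe sequence composition was not run, because probe sequences were not used here. Each array sets WT against overexpression in 1 ratio, so the limma fit is itself paired. Of the settings of each named gene, 2344 values kept direction and side of the threshold, 18 fell short of it, 2 passed it and 3 turned. Of the list values 438 kept theirs, 9 were lost, 7 gained and 2 turned. Array agreement stayed between 0.914 and 0.936.

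Agilent processed ratios gave 487 higher and 706 lower genes at least 2-fold changed. The values of the series, which are nearly these ratios with the sign reversed, gave 488 and 706 and are not a separate result. Normexp with offset 16 gave 329 and 513, against 287 and 455 with offset 50, so the main counts depend in part on the offset. The cause of the remaining difference was not tested. Median centring gave 513 higher such genes, 18 called lists against 11, and Hdac6 at 0.52. It turned the proteasome (0.39 above the mean of all genes) and mitosis (0.31) lists, Nanog (0.92) and Dmap1 (0.031), since it leaves the trend with brightness in place. Keeping outlier-marked spots turned Sp110 to 0.95; the cause was not tested. Without genes of chromosomes 1, 8 and 11, 277 genes were at least 2-fold lower, against 455 with them. Among genes above background in both channels, chromosomes 8 and 11 held 163 of the 414 that were at least 2-fold lower, where their share would give 57.0. For genes changed, the Feature Extraction error model on each array gave 1272 higher and 2045 lower, the added 2-fold condition 287 and 455, and limma against 1.5-fold 547 and 835. At 1.5-fold on both arrays 971 were higher and 1712 lower. Camera with an estimated correlation called 0 lists (0 at unadjusted p under 0.05), fry called 0 (7 at unadjusted p under 0.05), and matched random lists 12. The estimated correlation rests on 1 residual degree of freedom, which leaves that camera test little power. Fry's mixed test called 3. On 1 array alone, 328 to 627 genes were at least 2-fold higher and 547 to 716 lower, and Hdac6 was at 0.15 or -0.055, with replicate 1 left out giving the higher counts (627 and 716). One array leaves no residual degree of freedom, so these values carry no test and the limma and list counts have no such value.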

Other observations

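The scan of gene families was chosen after the results were seen. Families were formed from the symbols without their trailing number, and 272 families with at least 8 measured members were tested with camera at the preset correlation. At adjusted p under 0.05 were 14 families, 12 higher and 2 lower, and none with an estimated correlation (smallest adjusted p = 1.00). All 9 measured members of the Gbp family, guanylate-binding proteins induced by interferon, were lower by limma, with a median log2 ratio of -1.71 (adjusted p = 2.7e-04), and 0 of them lie on chromosomes 1, 8 or 11. In the Myh family of myosin heavy chains 9 of 11 members were lower and 2 higher (median -0.74, adjusted p = 0.048), with 5 of the 11 on those chromosomes.

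Families that were higher included the Ccl chemokines, with 11 of 16 members higher and 1 lower (median 0.63, adjusted p = 0.0026), although 12 of the 16 lie on chromosomes 1, 8 or 11. Of the S100a calcium-binding proteins 9 of 12 were higher and 2 lower (median 0.68, adjusted p = 0.0090), of the Serpinb family 8 of 14 higher and 2 lower (median 0.38, adjusted p = 0.028), and of the Bmp family 7 of 9 higher and 0 lower (median 0.44, adjusted p = 0.039). The clustered protocadherins Pcdhb had 7 of 10 higher and 0 lower (median 0.37, adjusted p = 0.011). The fibroblast (feeder) markers rose alongside these families (median 1.11, 23 of 25 higher), and S100a4 is itself in that list, as Ccl2 is among the NF-kB targets. Whether feeder RNA accounts for the rise of these families was not tested. Olfactory receptor genes (Olfr) had 33 of 117 higher and 9 lower, at a median of 0.078 (adjusted p = 0.022). Keratin-associated protein genes (Krtap) had 14 of 22 higher and 1 lower (median 0.29, adjusted p = 0.011). Over all 16062 genes, 3559 were higher and 5540 lower. A dye effect shared by dim probes was not tested as a source of these family calls.

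Chromosome 8 differed along its length. Each chromosome was divided in gene order into 10 segments. On chromosome 8 the 3 nearest its start had medians of -0.47, -0.45 and -0.53 and the last had -0.58, while the 6 between lay between -0.18 and -0.032. On chromosome 1 the 10 segments had medians between 0.14 and 0.37. Of the 170 segments of the other 17 chromosomes 1 lay at least 0.2 from their common median of -0.057, and these segments ranged from -0.22 to 0.18. With the Agilent processed ratios, the shifts against the other chromosomes were 0.29 for chromosome 1, -0.21 for chromosome 8 and -0.47 for chromosome 11. Median centring in place of loess gave 0.24, -0.15 and -0.38. No explanation was tested for chromosomes 1 and 8.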
